A study of Mus musculus with 2 samples.

How the data were processed

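The data are UMI counts per gene and cell barcode from 2 libraries of newborn mouse kidney. Per the labels, libraries were made on a droplet platform of 10x Genomics with 3′ chemistry. Per the submitters' processing notes, bcl2fastq 2.20.0, Cell Ranger and STAR 2.7.2a were used with genome build GRCm38 (mm10). Per the file headers, Cell Ranger was version 7.0.0 for the WT and 7.1.0 for the KO library. The deposited matrices hold raw integer counts, 1 matrix per library, with no barcode under 500 UMIs, so cells had been called before deposit. The annotation and the handling of intronic reads are not given in the sources used here. Of 55488 gene rows, 55141 had an identifier in the GENCODE M21 table, which gave positions on GRCm38, and 114 symbols stood on more than 1 row.

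Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, which left 4187 of 5572 WT and 5040 of 5991 KO barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its own threshold called 3 WT and 2 KO barcodes, under the 0.5% set beforehand as the smallest usable share, so the expected share of highest scores was removed, 192 WT and 256 KO barcodes.

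Counts were scaled per cell to 10000 and log-transformed, and 2000 variable genes were taken over both libraries without mitochondrial, ribosomal, haemoglobin, Xist and Y-linked genes. They gave 40 principal components, 20 nearest neighbours and Leiden clusters at resolution 1 (igraph 0.11.9), with no batch integration. Clusters were named from marker lists fixed before the data were examined. A name needed a mean marker score, scaled to the highest cluster, of at least 0.35 and a lead of 0.05 over the next list. These naming thresholds were set after seeing the data. Clusters that failed them, had low UMIs without own markers, or had leading genes of another list stayed unnamed, 414 WT and 391 KO cells. 6 classes of the Six2 lineage (progenitor, early nephron, podocyte, proximal tubule, loop of Henle, distal tubule) and 6 outside it (ureteric bud and collecting duct, intercalated, stroma, mural, endothelium, immune) were compared. Intercalated cells (41 WT, 14 KO) were counted but their genes were not named.

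UMIs were summed over the cells of a class in each library and expressed as CPM of nuclear-encoded UMIs. Ratios are KO over WT with exact conditional 95% intervals, and shares carry exact Clopper-Pearson intervals. Log2 ratios had 0.5 UMI added to each sum. Named genes needed 50 UMIs over both libraries and 20 CPM in 1, and were ranked by the interval bound nearest to 1. The 12 highest and 12 lowest in loop of Henle cells, 6 of each in other nephron classes and 3 of each outside are eligible to be named, with Flcn, Fnip1, Fnip2, Tfeb, Tfe3, Mitf and Tfec always reported. Ribosomal, haemoglobin, mitochondrial, Xist, Y-linked and unnamed gene models were left out of the ranking. A class's own markers are not reported as differences of that class. The 8 highest and 8 lowest genes are given for the difference between loop of Henle cells and the outside classes.

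Gene lists, fixed before the data were examined, were summarised by the median over members with at least 10 UMIs, with an exact interval of the median from its members' ranks, and by its percentile among 10000 random lists matched on expression in 20 bins. The interval describes members, which are not independent replicates. With 1 library per group no test across samples was possible and none was made. A cell counted as cycling with at least 2 UMIs over the mitosis list after thinning to 3000 UMIs.

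Simulated sums for the loop of Henle class, with 200 genes changed by known folds, were used to check the calculation of intervals and percentiles. They were drawn with counting error alone (Poisson), the model the interval assumes, and held no variation between cells or animals. They therefore do not show how often the intervals hold in real libraries. The interval held 1 for 96.1% of unchanged genes among the 12574 with enough UMIs, and excluded it on the right side for 89.6% of 67 genes changed 1.5-fold and 100% of 65 genes changed 2-fold.

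Alternatives varied the mitochondrial limit, the cell filter, the doublet removal, the Leiden resolution, clusters found in the WT library alone, scaling by TMM (edgeR 4.0.16) or median of ratios (DESeq2 1.42.0), averaging over cells or clusters, thinning, and the minimum UMIs of genes. Clustering without markers and differing genes (4083 genes left out), proximal tubule without a cluster held at 90% or more by 1 library, and equal weights for outside classes were added after seeing the data. The same settings were run for lists in the outside classes, and for more lists in nephron classes, also chosen after seeing the data. TMM and median-of-ratios scaling shifted log2 ratios in loop of Henle cells by 0.07 and 0.08, and by at most 0.10 in size in every class. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and in R 4.3.3.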

Results

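Single-cell RNA-seq was carried out on kidneys of newborn mice (postnatal day 0) in which Six2-Cre, a recombinase active in nephron progenitors and inherited by the nephron epithelium they form, deleted a floxed Flcn gene. Flcn encodes folliculin, a tumour suppressor that acts on the lysosome with its partners FNIP1 and FNIP2 and restrains the transcription factors TFEB and TFE3. There were 2 libraries, 1 labelled Flcn WT and 1 labelled Flcn KO. The design text describes the first as heterozygous and the second as homozygous for the floxed allele, so the WT library also carried Cre. The number of animals behind each library is not given, and the tissue label reads embryonic kidney. The WT library held 5572 barcodes with 147390790 UMIs and the KO library 5991 barcodes with 149679281 UMIs. After filtering, 3995 WT cells (median 20972 UMIs) and 4784 KO cells (median 18443.5 UMIs) remained. With 1 library per group no difference below has a replicate check, and every interval covers counting error only.

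Flcn, the targeted gene (ENSMUSG00000032633, chromosome 11, 59791408 to 59810016, minus strand, GRCm38), had 1551 UMIs in the WT library and 1413 in the KO library. In the loop of Henle class it had 55 WT and 107 KO UMIs, a CPM ratio of KO over WT of 1.38 (95% interval 0.990 to 1.95). The ratio was 0.531 (0.444 to 0.633) in proximal tubule, 1.80 (1.37 to 2.37) in podocytes, 1.10 (0.874 to 1.38) in nephron progenitors and 0.980 (0.864 to 1.11) in the pooled classes outside the Six2 lineage. The libraries were counted at the 3′ end of transcripts and the floxed exons are not named in the labels, so these counts do not check the deletion.

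The first comparison asked how the kidney's cell classes were represented. Stroma made up 28.6% of WT cells (1141 cells, exact interval 27.2 to 30.0%) and 41.8% of KO cells (2000 cells, 40.4 to 43.2%). Podocytes, the filtering cells of the glomerulus, were 4.73% (189 cells, 4.09 to 5.44%) against 2.30% (110 cells, 1.89 to 2.76%), and ureteric bud and collecting duct cells, which do not descend from Six2-positive progenitors, 4.61% (184 cells) against 1.73% (83 cells). Endothelium was 6.58% against 8.72%, mural and mesangial cells 3.00% against 4.89%, and macrophages and other immune cells 1.33% against 2.61%. Loop of Henle cells, the class the study is about, were 3.80% (152 cells, 3.23 to 4.45%) against 4.18% (200 cells, 3.63 to 4.79%). Their shares depended on the settings. They were 2.52% against 3.53% with at most 10% mitochondrial UMIs, and 8.26% against 6.96% at Leiden resolution 0.5, which merges in distal cells.

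Nephron progenitors were 16.4% of WT and 12.5% of KO cells, and early nephron cells, from committing progenitor to S-shaped body, 5.56% and 3.68%. Several class markers themselves differed at least 2-fold between the libraries, namely 6 of 12 in loop of Henle, 5 of 10 in distal tubule, 4 of 16 in proximal tubule and 4 of 9 in intercalated cells. Clustering was therefore repeated without the markers and without the genes that differ, an alternative chosen after seeing the data. It gave proximal tubule cells at 8.79% against 6.06% and loop of Henle cells at 4.86% against 4.64%, which then included 55 WT and 31 KO cells of the distal class (107 and 95 others joined early nephron cells), and left stroma at 28.9% against 42.3% and podocytes at 4.23% against 2.26%. Cells without a name were 10.4% of the WT and 8.17% of the KO library. Over 20% mitochondrial UMIs removed 17.7% of WT and 11.6% of KO barcodes, and classes differ in the loss such a filter brings. The shares describe what was recovered from each dissociation.

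**Figure D1:**
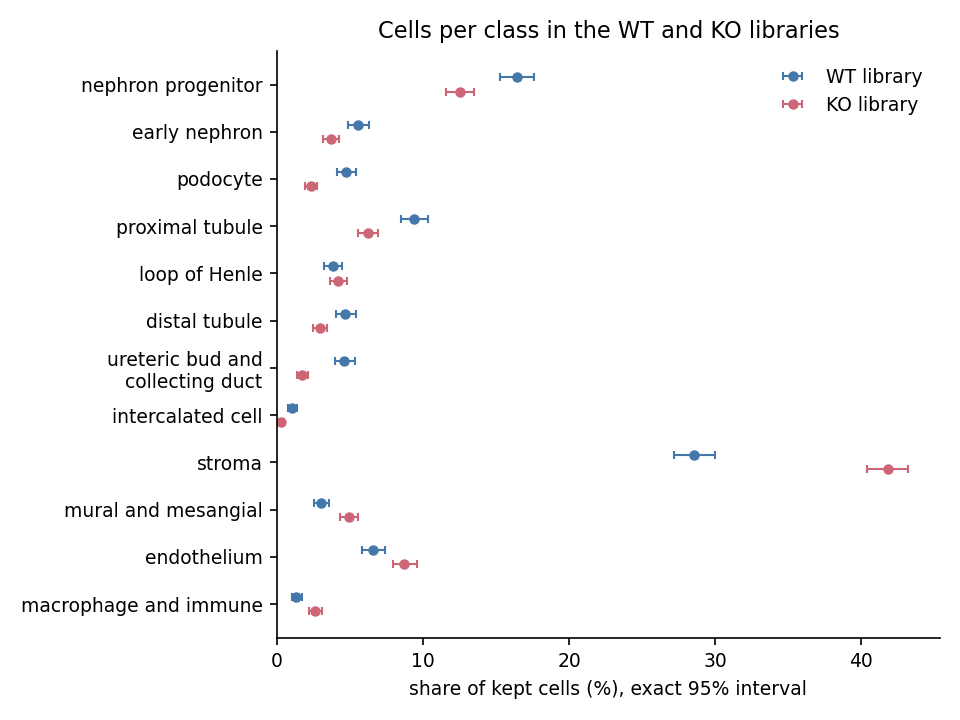
Share of kept cells (%) by class in the WT library (3995 cells) and the KO library (4784 cells), with exact 95% binomial intervals. Stroma lay at 28.6% in WT and 41.8% in KO, and loop of Henle cells at 3.80% and 4.18%.

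The main comparison asked what expression differs in loop of Henle cells between the libraries labelled Flcn KO and Flcn WT. In these cells the KO library had higher levels of Gpnmb, a lysosomal glycoprotein and TFEB/TFE3 target, with 11 WT and 621 KO UMIs (ratio 40.1, interval 22.3 to 80.8), and of Nkx6-2, a homeobox transcription factor, with 1 WT and 647 KO UMIs (ratio 460, interval 82.3 to 18199). Hexa, a subunit of the lysosomal enzyme beta-hexosaminidase, was 8.54-fold higher (7.36 to 9.96) and Atp6v0d2, a subunit of the vacuolar proton pump, 6.77-fold higher (5.75 to 8.02). Sgcz, which encodes a sarcoglycan, had 9506 WT and 145 KO UMIs (ratio 0.0109, 0.00914 to 0.0128), and Ranbp3l 2447 and 63 UMIs (ratio 0.0183, 0.0140 to 0.0235). Ranbp3l was also lower in ureteric bud and collecting duct, outside the Six2 lineage (ratio 0.0441), so its lower level is not particular to loop of Henle cells. The class held 152 WT and 200 KO cells in 1 cluster, with median depths of 41954 and 50957 UMIs.

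The other genes at the top of the ranking were Bhlhe41, a transcriptional repressor of the circadian system (ratio 15.9, 9.66 to 28.1), L3mbtl4 (12.5), Slc26a10 (11.6), Angptl2, a secreted glycoprotein (11.5), Antxr1 (9.05), Dpp7, a lysosomal dipeptidase (8.47), Rab27a, a GTPase of secretory lysosome-related organelles (8.29), and Ass1, an enzyme of arginine synthesis and a marker of proximal tubule (7.68). At the bottom stood Wnt11, a secreted Wnt ligand of the ureteric bud tips (169 WT and 5 KO UMIs, ratio 0.0210, 0.00674 to 0.0501), Nccrp1 (0.0231), Chrm3, a muscarinic acetylcholine receptor (0.0435), Grm8, a glutamate receptor (0.0449), and Mapk10, a JNK kinase (0.0481). Unc5d, a netrin receptor (0.0636), Pde10a, a phosphodiesterase (0.0691), Frmpd4 (0.0716), Ntn4, a netrin (0.0815), and the forkhead factor Foxq1 (0.0825) completed the list.

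Of the folliculin partners in loop of Henle cells, Fnip2 was 5.65-fold higher in KO (488 and 3877 UMIs, 5.14 to 6.22) and Fnip1 1.71-fold higher (1.56 to 1.87). Tfeb itself was at 0.980 (0.873 to 1.10), Tfe3 at 1.22 (0.980 to 1.53) and Mitf, a related factor, at 0.749 (0.703 to 0.797). Tfec had 1 UMI in each library. Outside the Six2 lineage Mitf was at 0.726 in ureteric bud and collecting duct, 0.700 in mural cells and 0.490 in immune cells. It was at 1.02 in stroma and 1.12 in endothelium, so its lower level is not particular to loop of Henle cells. In nephron progenitors Mitf was 2.45-fold higher in KO (2.14 to 2.80).

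A UMI of Gpnmb was found in 46.5% of KO and 3.29% of WT loop of Henle cells, and after thinning each cell to 3000 UMIs in 8.72% and 0.699%. In endothelium, which should lack it, the shares were 1.20% and 1.14% unthinned at median depths of 25779 and 23893 UMIs, and 0 of 412 KO and 0 of 262 WT cells thinned. Nkx6-2 was seen in 42.5% of KO and 0.658% of WT loop of Henle cells (thinned 11.3% and 0 of 143), against 0.719% and 0.380% of endothelial cells unthinned. For Sgcz the shares were 18.0% of KO and 66.4% of WT cells (thinned 3.59% and 45.5%), with 10.8% and 13.3% in endothelium (thinned 3.64% and 4.20%), so the KO share after thinning lay at that background.

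**Figure D2:**
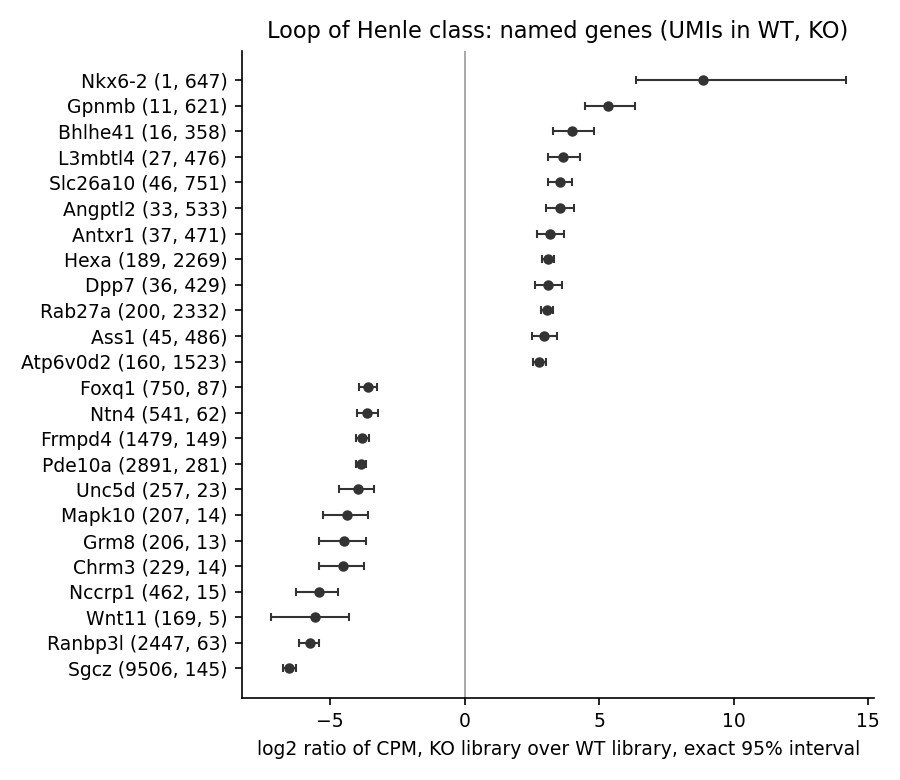
Log2 ratio of CPM (KO over WT library) with its exact 95% interval for the 12 highest and 12 lowest ranked genes in the loop of Henle class, with UMIs in the WT and KO libraries after each symbol. Sgcz (9506 and 145 UMIs) and Nkx6-2 (1 and 647 UMIs) lie at the ends.

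Gene lists fixed beforehand were summarised in loop of Henle cells by the median log2 ratio of their members. All 17 TFEB and TFE3 targets tied to the FLCN pathway were higher in KO (median 0.87, interval over members 0.73 to 1.68), 15 of them at least 1.5-fold, among them Amdhd2 (ratio 3.71), Rragd, a Rag GTPase that recruits mTORC1 to lysosomes (3.20), and Sqstm1, an autophagy receptor (2.39). Of 35 lysosomal hydrolases and membrane proteins, 34 were higher (median 0.71, 0.63 to 0.84), with Arsa, arylsulfatase A, at 5.06, Grn, progranulin, at 2.68 and Neu1, a sialidase, at 2.15. All 15 vacuolar ATPase subunits were higher (median 0.61, 0.42 to 0.95), led by Atp6v1b2 (3.19). As a description of these libraries, each of the 3 medians lay at percentile 100 of 10000 random lists matched on expression.

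Cell cycle genes went the other way in these cells. Of 20 genes of DNA replication, 2 were higher in KO and 16 at least 1.5-fold lower (median -1.14, -1.42 to -0.65, percentile 0), with Mcm3, a subunit of the replicative helicase, at 0.279 (0.227 to 0.342) and Hells at 0.289. This list was also lower in KO in stroma (-0.59, 20 of 20 members lower), mural cells (-0.54), nephron progenitors (-0.51, 20 of 20 lower) and endothelium (-0.30, 20 of 20 lower), and higher in ureteric bud and collecting duct (0.26, 17 of 20 higher, but -0.051 as a mean over cells) and in the few intercalated cells (1.36). Of 24 mitosis genes 1 was higher (median -0.61, -0.87 to -0.47, percentile 0), with Top2a at 0.431 (0.384 to 0.484) and Mki67 at 0.569. Keeping the doublet calls brought the mitosis median to -0.28 and averaging over cells to -1.03. Counted per cell, after thinning to 3000 UMIs, 37 of 143 WT cells (25.9%, 18.9 to 33.9%) and 43 of 195 KO cells (22.1%, 16.4 to 28.5%) had at least 2 mitosis UMIs, and 9 WT and 5 KO cells were too shallow. At 1500 UMIs the shares were 21.2% (14.9 to 28.8%) and 11.6% (7.47 to 16.8%), so the gap depended on the depth chosen. Unthinned shares were 74.3% and 81.0%, and thinned proximal tubule cells, as background, gave 0.809% of 371 and 1.36% of 295 at median depths of 42612.5 and 50459 UMIs.

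Genes of thick ascending limb transport and differentiation had a median of -0.41 (-0.74 to 0.12, percentile 0) with 6 of 20 members higher, 2 of them at least 1.5-fold, and 9 at least 1.5-fold lower. 8 of the 20 are markers that name the class. The other 12 had a median of -0.29 (-0.73 to 0.13), 4 of them higher, and clustering without the markers and differing genes gave -0.40 for the whole list. The list was also lower in the pooled classes outside the Six2 lineage (-1.02, or -0.31 with those classes weighted equally). Its lower level is therefore not particular to loop of Henle cells.

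Nuclear-encoded oxidative phosphorylation genes were higher in KO in 27 of 28 cases (median 0.34, percentile 99.95) and glycolysis genes in 13 of 16 (0.30, percentile 98.9), although Slc2a1, the glucose transporter GLUT1, was lower (0.619). Ribosomal protein genes were higher in 6 of 87 cases (median -0.27, percentile 0). The autophagy list had a median of 0.18 (percentile 96.7, 19 of 25 higher) and the tubule injury list 0.37 (percentile 99.9, or 0.39 with a gene at 0 set to 3 counts). The injury members went both ways, with Cd44 at 2.88 and Anxa3 at 3.11 but Anxa1 at 0.0878 and Clu, clusterin, at 0.291, and after thinning the median was -0.02. Medians within the middle 95% of random lists were found for the amino acid response (-0.01, percentile 54.1), endoplasmic reticulum stress (0.09, 70.3), oxidative stress (0.03, 62.2), interferon (0.02, 73.9), sterol and fatty acid synthesis (0.11, 89.4), dissociation response (0.11, 76.6), extracellular matrix (-0.10, 28.8) and proximal tubule (-0.29, 28.8) lists. Mitochondrially encoded genes were 6.35% of WT and 6.63% of KO UMIs in the class.

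**Figure D3:**
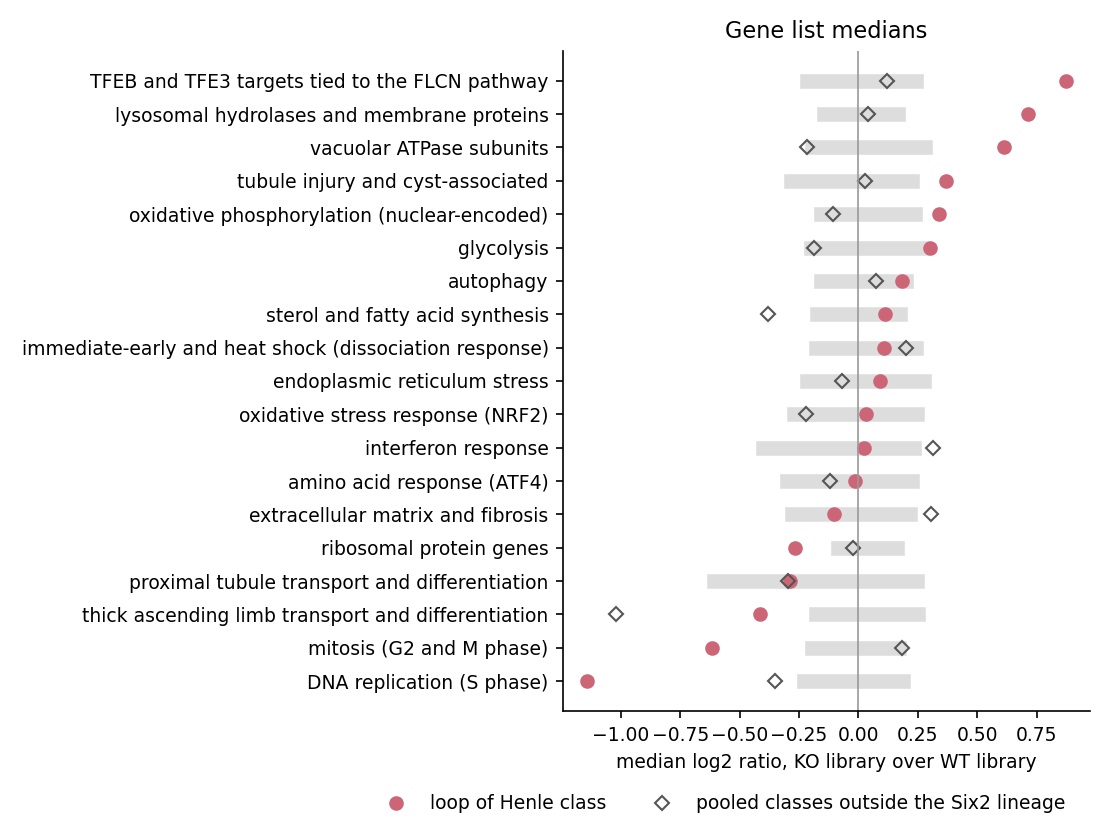
Median log2 ratio (KO over WT library) of each gene list in the loop of Henle class (filled) and in the pooled classes outside the Six2 lineage (open), with grey bars for the middle 95% of 10000 matched random lists in the loop of Henle class. The list of TFEB and TFE3 targets lies at 0.87 in loop of Henle cells and 0.12 outside.

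The same question was asked of the other classes of the Six2 lineage. The lysosomal list was higher in KO in each, with medians of 0.53 (0.32 to 0.63) in nephron progenitors, 0.55 (0.37 to 0.66) in early nephron cells, 1.02 (0.84 to 1.24) in podocytes, 0.60 (0.38 to 0.85) in proximal tubule and 0.82 (0.56 to 0.95) in distal tubule. TFEB and TFE3 targets had medians of 0.52, 0.41, 1.02, 0.72 and 0.73 in the same order, and vacuolar ATPase subunits 0.32, 0.49, 0.80, 0.39 and 0.51. Over the alternatives the early nephron TFEB and TFE3 median ranged from 0.39 to 0.74 and the distal vacuolar ATPase median from 0.22 to 0.61. Gpnmb had 0 WT and 214 KO UMIs in proximal tubule cells (at least 76.7-fold with the 0 set to 3 counts), Rragd was 5.35-fold higher there and 4.90-fold (4.22 to 5.71) higher in podocytes, and Fnip2 3.52-fold (2.73 to 4.57) higher in podocytes and 3.24-fold (2.94 to 3.57) higher in distal tubule.

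Apoe, a lipid-carrying apolipoprotein, was among the 6 highest genes in 4 of these classes, at 6.37-fold in nephron progenitors, 5.42-fold in early nephron cells, 33.4-fold (22.9 to 50.8) in podocytes and 13.7-fold in distal tubule. Uap1l1 was 6.58-fold higher in progenitors, 8.98-fold in early nephron cells and 11.7-fold in distal tubule. Podocytes of the KO library also had more Ptgds, prostaglandin D synthase (21 WT and 2087 KO UMIs, ratio 174, 114 to 282), and Lama3, a laminin chain (1 and 330 UMIs, ratio 578, 103 to 22902), and less Ntrk3, a neurotrophin receptor (421 and 3 UMIs, ratio 0.0125, 0.00256 to 0.0367). Among the lowest genes were Grm7, a glutamate receptor (0.0886), and Dkk2, a Wnt pathway antagonist (0.147), in early nephron cells, and Chst9 (0.208), Npy, a neuropeptide (0.217), and the imprinted Meg3 (0.296) in progenitors. In distal tubule the transcripts S100a8 and S100a9, abundant in neutrophils, were higher in KO (2 and 223, 8 and 361 UMIs). The KO library also held a larger immune share, and whether that bears on these transcripts was not tested.

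Proximal tubule cells of the KO library had higher levels of injury genes, with 18 of 19 members higher (median 1.69, 0.72 to 2.72, percentile 100). Havcr1, which encodes kidney injury molecule KIM-1, was 22.2-fold higher (18.3 to 27.2), Krt19 11.0-fold and Plaur, the urokinase receptor, 10.2-fold. Sprr1a (ratio 93.0, 54.1 to 175), Nupr1, a stress-induced nuclear protein (63.6, 45.8 to 91.1), Cldn4, a tight junction claudin (47.3), S100a6 (45.8), the cytokine Il34 (33.8) and Akap12 (31.8) ranked highest there among genes with at least 20 CPM in 1 library. All 18 interferon response genes were higher (median 1.68, 1.22 to 2.83, or 1.73 with a gene at 0 set to 3 counts), Isg15, a ubiquitin-like protein, at 27.3 (11.4 to 85.6) and Bst2, tetherin, at 7.14. None of the 22 genes of proximal tubule transport and differentiation was higher (median -0.76, -1.20 to -0.40), with Slc22a8, the organic anion transporter OAT3, at 0.294 and Pck1, an enzyme of gluconeogenesis, at 0.284. Of these 22, 9 are class markers, and the median of the other 13 was -0.61. Sterol and fatty acid synthesis genes were lower in 23 of 25 cases (median -0.74), with Insig1, a regulator of sterol synthesis, at 0.387. That list was also lower in nephron progenitors (-0.48), mural cells (-0.41), endothelium (-0.19) and stroma (-0.18), and higher in distal tubule (0.30) and immune cells (0.51).

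Clusters 13 (272 WT and 261 KO cells) and 22 (102 and 36 cells) made up the proximal tubule class. At finer resolution 1 of its clusters held 3 WT and 179 KO cells, and without it the injury median was 0.54 and the interferon median 0.77, while the transport median was -0.58, the sterol median -0.39 and the lysosomal median 0.42. Over all alternatives the injury median ranged from 0.54 to 1.94. Havcr1 was seen after thinning in 20.3% of 295 KO and 1.08% of 371 WT proximal tubule cells, against 0.243% of 412 KO and 0 of 262 WT endothelial cells, and unthinned in 53.5% and 15.5%. The dissociation response list was also higher in these cells (median 0.38, 0.26 to 0.73, 18 of 18 higher), and stood at 0.56 without that cluster.

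**Figure D4:**
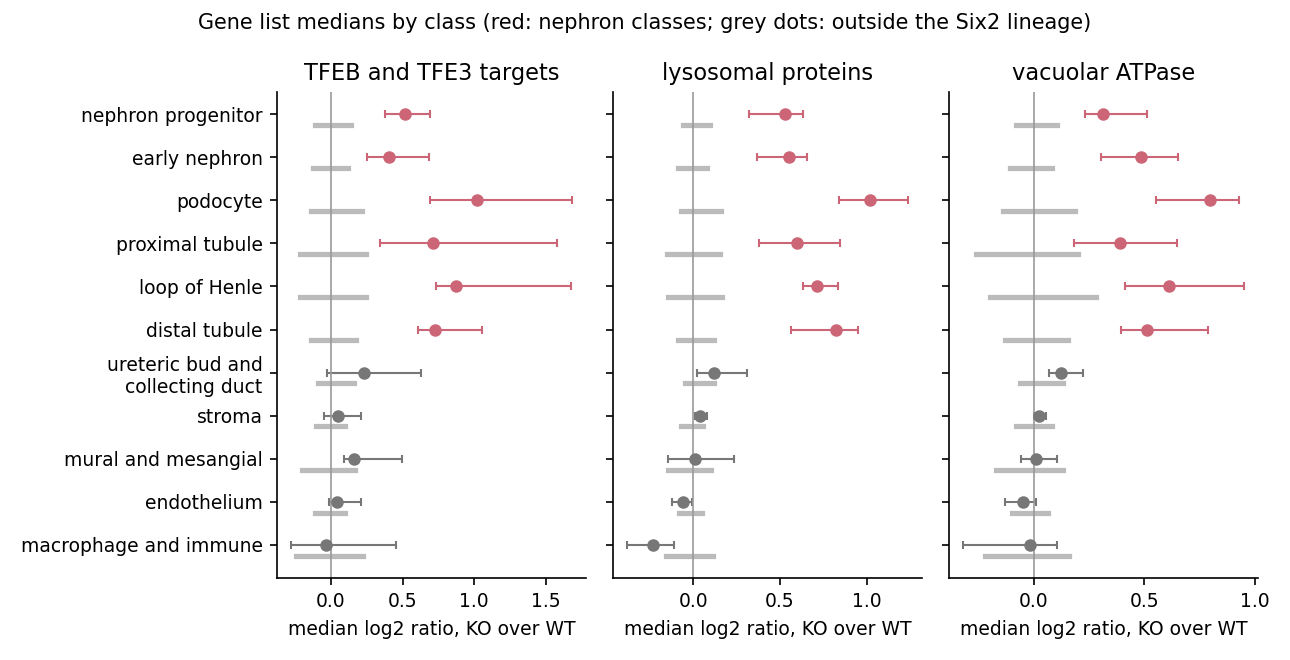
Median log2 ratio (KO over WT library) of 3 gene lists by class, with the exact 95% interval of the median over list members and grey bars for the middle 95% of matched random lists. Nephron classes (red) reach 1.02 for the lysosomal list in podocytes, while the 5 classes outside the Six2 lineage shown (grey dots, intercalated cells left out) lie at or below 0.12 for that list.

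Classes outside the Six2 lineage served as background within the same libraries. Pooled, they gave medians of 0.12 (percentile 98.9) for TFEB and TFE3 targets, 0.04 (93.5) for the lysosomal list and -0.22 (0) for vacuolar ATPase subunits. Gpnmb had 0 WT and 29 KO UMIs in ureteric bud and collecting duct (at least 20.9-fold with the 0 set to 3 counts) and 6 and 33 in stroma (ratio 3.20, 1.32 to 9.33). TFEB and TFE3 targets had a median of 0.23 in ureteric bud and collecting duct (percentile 99.8, 12 of 16 higher, Rragd at 1.82), 0.16 in mural cells (percentile 97.4, 12 of 15 higher), 0.05 in stroma, 0.04 in endothelium and -0.04 in immune cells. By class the lysosomal median was 0.12 in ureteric bud and collecting duct, 0.04 in stroma, 0.01 in mural cells, -0.06 in endothelium and -0.23 in immune cells. The 41 WT and 14 KO intercalated cells had the highest, 0.26 (0.11 to 0.38). The largest stroma cluster was cluster 1 in WT (279 WT and 327 KO cells) and cluster 2 in KO (175 and 535 cells).

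The difference between loop of Henle cells and this background, in log2 ratio, was 0.97 as a median over TFEB and TFE3 targets, 0.67 over lysosomal genes and 0.79 over vacuolar ATPase subunits, -0.80 over DNA replication genes and -0.83 over mitosis genes. Fewer ureteric and intercalated cells in the KO library shift the pool itself, as the thick ascending limb list shows (-1.02 pooled, -0.31 with the classes weighted equally). With equal weights, chosen after seeing the data, the differences were 0.83, 0.74, 0.65, -0.88 and -0.74 for these lists in the same order. Among single genes the difference was largest on the higher side for Nkx6-2 (6.74), Atp6v0d2 (4.23), Slc34a2, a phosphate transporter (3.96), Bhlhe41 (3.76), Ass1 (3.63), Slc26a10 (3.50), Arg2, a mitochondrial arginase (3.46), and Arhgdig (3.28). Slc34a2 was not higher in loop of Henle cells (286 WT and 357 KO UMIs, log2 ratio -0.17), and its difference rests on 19 WT and 1 KO UMIs outside. The outside log2 ratio was also below 0 for Atp6v0d2 (-1.48), Ass1 (-0.70) and Arg2 (-0.98). The difference was lowest for Sgcz (-6.20), Nccrp1 (-5.17), Wnt11 (-4.73), Mapk10 (-4.49), Unc5d (-4.12) and Chrm3 (-3.95). Next came Prox1, a homeobox factor (-3.73, with 499 WT and 75 KO UMIs in loop of Henle cells), and Robo2, a receptor for Slit ligands (-3.71). The WT and KO files came from different Cell Ranger versions, 7.0.0 and 7.1.0, 1 per genotype.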

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

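All tests of explanations in this part were chosen after the results were seen. For 2 gene lists the loop of Henle class and the classes outside the Six2 lineage stood on opposite sides of their matched random lists and kept opposite signs with the outside classes weighted equally. Vacuolar ATPase (0.61 against -0.22) and glycolysis genes (0.30 against -0.19) were opposed in the pool but not with equal weights (0.04 and 0.05). Mitosis genes had a median log2 ratio of -0.61 in loop of Henle cells against 0.18 in the pooled outside classes (0.07 with equal weights), and nuclear-encoded oxidative phosphorylation genes 0.34 against -0.11 (-0.02 with equal weights). The outside classes differ among themselves for mitosis genes, at 0.43 in immune cells, 0.21 in ureteric bud and collecting duct, 0.19 in stroma, -0.01 in endothelium and -0.36 in mural cells (22 of 24 lower), and at 0.87 in the few intercalated cells. Podocytes, of the Six2 lineage, lay above the pooled outside classes for mitosis genes (difference 0.29, 16 of 22 members higher). Early nephron cells (-0.11), nephron progenitors (-0.27), proximal tubule (-0.66) and distal tubule (-0.70) lay below. The mitosis contrast is thus not shared by all nephron classes. For oxidative phosphorylation genes the outside classes ran from -0.12 in mural cells to 0.09 in the few intercalated cells. Proximal tubule, of the Six2 lineage, stood at -0.32 (26 of 28 lower) and lay below the pooled outside classes (difference -0.20). Distal tubule (0.41), podocytes (0.38), early nephron cells (0.14) and nephron progenitors (0.09) lay above them. The oxidative phosphorylation contrast is thus shared by most nephron classes but not by proximal tubule. With 1 library per group these differences between classes were not tested.

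For the lysosomal list, higher in the KO library in 6 nephron classes, a difference between the libraries as a whole, Cell Ranger version included, would raise the list in other classes too, and the highest median among 5 outside classes was 0.12, below the lowest lower bound of the nephron classes, 0.32. Intercalated cells, left out of this test for their 14 KO cells, stood at 0.26 (0.11 to 0.38), which weakens it. Clusters drawn by the genes that differ were tested in loop of Henle cells only. Clustering without those genes gave a median of 0.75 there, above the lower bound of 0.63, which argues against that explanation for this class alone. The class kept 139 of 152 WT and 191 of 200 KO cells, so nearly the same cells were compared, and took in 55 WT and 31 KO distal cells. The distal class was not found in that clustering. Macrophage transcripts would have to reach a median of 24.0% of their macrophage level in KO loop of Henle cells to give the lysosomal values, and 12 macrophage markers stood at a median of 0.0363%. What stays open is a candidate explanation by loss of Flcn itself, which the genotype labels name. Differences between animals go with the genotype here and stay open too. Litter and day of dissociation are not given in the sources used here, so they may go with it as well.

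Injury and interferon lists were higher in KO proximal tubule cells. Cells or RNA of 1 other named class would bring that class's markers. Over the 11 other classes these reached at most 3.32% of the level needed by the injury members at least 1.5-fold higher in KO. The level needed lay below the class's own level only for immune cells (19.2%) and intercalated cells (79.8%). Their markers stood at medians of 0.0193% and 0.00810% of their own level. For the other classes the median level needed exceeded the class's own, from 105% for ureteric bud and collecting duct to 1047% for podocytes. Cells of such a class alone would not reach that median. For the injury members as a set this argues against these classes as the source, only narrowly for ureteric bud and collecting duct. Some outside classes shared the direction, with the interferon list at 0.67 in ureteric bud and collecting duct (15 of 18 higher) and the injury list at 0.37 in stroma, while the interferon list was at -0.16 in endothelium. A stronger dissociation response in the KO library could not be excluded, because the dissociation list was higher as well (median 0.38, upper bound 0.73, against a lower bound of 0.72 for the injury list), and also in endothelium (0.26), stroma (0.22) and mural cells (0.21), although in endothelium the injury list stood at -0.09. Both this and a difference in the tubules before dissociation, whether from Flcn loss or from the condition of the animals, remain possible.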

How the results depend on the processing

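The clustering without markers and differing genes, the proximal tubule class without 1 cluster and the equal weights for outside classes were chosen after seeing the data. No paired analysis was possible because each group has 1 library. TFEB and TFE3 targets stayed higher in KO in the 6 nephron classes under each alternative in which the class was found (distal tubule was not found in some), from 0.39 to 1.06, the lysosomal list from 0.42 to 1.06 and the vacuolar ATPase list from 0.22 (distal tubule) to 0.89. Of 911 alternative values of list medians, 826 stayed within the interval over members, 81 moved out of it and 4 changed sign. These were the injury list in loop of Henle cells, at -0.018 after thinning, and in ureteric bud and collecting duct the DNA replication list, at -0.051 as a mean over cells, and the lysosomal list, at -0.032 without a cell filter and -0.011 with clusters from the WT library. Of 65 lineage differences 60 stayed within the interval over members. Class shares depended more on the settings. Of 122 alternative values of shares, loop of Henle and distal tubule included, 64 stayed within the counting interval and 58 moved out of it. Of 288 values of single named genes 225 stayed within the counting interval and 0 changed sign. Averaging within clusters cannot change a value in loop of Henle cells or in any other class formed by 1 cluster. Those values are counted among the list medians and single named genes that stayed. Where a value moved the cause was not tested.

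At most 10% mitochondrial UMIs gave loop of Henle shares of 2.52% in WT and 3.53% in KO, and early nephron medians of 0.73 (TFEB and TFE3 targets) and 0.68 (lysosomal). Without a cell filter the early nephron lysosomal median was 0.71 and the loop of Henle mitosis median -0.45. With doublet calls kept these were 0.67 and -0.28, the early nephron TFEB and TFE3 median 0.74 and the proximal tubule interferon median 0.84. At Leiden resolution 0.5, which merges loop of Henle and distal cells, the shares were 8.26% and 6.96%, the lysosomal median 0.85 and the DNA replication median -0.56, and 12 of the 24 named genes were shared. At resolution 2 the early nephron lysosomal median was 0.74. Clusters from the WT library gave early nephron medians of 0.71 and 0.72. Clustering without markers and differing genes gave a WT share of 4.86%, an early nephron lysosomal median of 0.73 (with 107 WT and 95 KO distal cells in that class) and 14 shared named genes. The mean over cells gave a mitosis median of -1.03. Thinning to 3000 UMIs kept 8 named genes and gave 0.54 for TFEB and TFE3 targets in distal tubule, and a minimum of 10 UMIs without a CPM minimum kept 15. Without the cluster held by the KO library, proximal tubule medians were 0.54 (injury) and 0.77 (interferon).

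Shares of loop of Henle cells with mitosis UMIs in WT and KO were 74.3% and 81.0% unthinned, 45.5% and 41.5% with at least 1 UMI, 16.8% and 11.8% with at least 4, and 21.2% and 11.6% at 1500 UMIs. Distal tubule shares moved by more than 1.5 times, down to 2.25% and 0.789%, and are not compared. Depth limits intercalated cells, with 14 in the KO library, and genes with a few UMIs.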

Other observations

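Classes outside the Six2 lineage had differences of their own. Zbtb16, a zinc finger transcription factor, was 4.67-fold higher in KO stroma (interval 4.35 to 5.01) and 5.52-fold higher in KO endothelium (4.98 to 6.13). Stroma of the KO library also had more C7, a complement component (ratio 7.53), and Mdga2 (6.60), and less Il1rapl2 (0.231), while KO endothelium had more Reln, a secreted glycoprotein (6.38, 5.08 to 8.09), and less Cryab, a small heat shock protein (0.0303, 0.0149 to 0.0552). In ureteric bud and collecting duct cells, Sprr2f was 10.3-fold higher in KO (9.34 to 11.3) and Ranbp3l had 1472 WT and 30 KO UMIs (0.0441, 0.0297 to 0.0633). Slc12a1, the sodium transporter of the thick ascending limb, had 745 WT and 16 KO UMIs in that class. KO immune cells had more Lyve1, a hyaluronan receptor (6.88, 4.81 to 10.2), and S100a9 (5.50). An unnamed cluster of low depth with leading genes Retnlg and Stfa2 held 19 WT and 70 KO cells.

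S100g, the calcium-binding protein calbindin-D9k of distal tubule, had 74625 UMIs in the WT and 10919 in the KO library. It was lower in KO in classes that should lack it, at 0.163 (0.144 to 0.184) in stroma, 0.154 (0.119 to 0.198) in endothelium and 0.165 (0.132 to 0.205) in nephron progenitors. In early nephron cells it stood at 0.813 and in ureteric bud and collecting duct at 0.726.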
